A study of Rattus norvegicus with 6 samples.

How the data were processed

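Liver tissue of rats (Rattus norvegicus) was measured by RNA sequencing in 6 libraries, 3 of the untreated HCC group and 3 of the TAE group, and samples were grouped by their titles and descriptions. Per the labels' protocols, RNA was extracted with TRIzol, enriched for mRNA by poly(A) selection and made into strand-specific libraries by the dUTP method, which were sequenced as paired ends. The labels call the replicates biosamples and do not say that each came from a separate animal, so p-values measure the spread between these samples only, which may be technical. No 2 replicates agreed within sampling noise: chi-square per degree of freedom between replicates was 5.83 to 14.2 within HCC and 52.2 to 214 within TAE.

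The authors deposited 1 table of the whole series, and per the file headers it holds a raw read count and an FPKM value per gene and sample, with Ensembl gene identifiers, symbols, coordinates, exonic gene sizes and GO and KEGG terms. The deposited FPKM values equal the count scaled to the exonic size in kilobases and to the sample's total count (100% of values within 0.006 when recomputed). The submitters' processing notes name the build mRatBN7.2. The aligner, the counting tool, its use of strand and the treatment of reads that match several genes are not given in the sources used here. Gene ends on chromosome 1 of the table reach 282724300, which exceeds that chromosome in mRatBN7.2, so the build of the coordinates is not settled, and they are printed as the table gives them. Genes of multigene families, and overlapping or antisense genes, are uncertain as single genes. The reference given was a gene table of the GRCr8 assembly without sequence, used for older symbols only, so GC content was not checked.

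The design fixed before the data were examined named limma on log2(FPKM + 1) as the test, unless the file held counts. Because counts were present, edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, TMM scaling, filterByExpr, trended dispersion) on the deposited counts was the main test and limma (3.58.1) on FPKM with a mean FPKM of at least 0.5 an alternative. The contrast was TAE minus HCC, two-sided, without a block, with Benjamini-Hochberg adjustment over 14499 genes and a threshold of 0.05. Standard errors of log2 changes are approximate and were taken as the absolute change divided by the square root of the quasi-likelihood F. The biological coefficient of variation was 0.240. FPKM means and SDs are over 3 libraries per group.

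Gene lists (33 lists with 580 entries) were fixed before the data were examined. By symbol, 553 entries matched a gene of the table, 0 more by an older symbol, and 27 had no match and were not analysed here, among them Pecam1, Gapdh, Ahsg, H19, Col1a2, Ccr2 and Timd4. Lists with at least 5 tested members (29 lists) were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Of these, 18 passed, 13 higher and 5 lower in TAE, 0 held with an estimated correlation (1 of the 29 lists had an unadjusted p under 0.05), and 1 passed with fry, which asks whether the genes of a list move 1 way on balance and does not compare them with other genes. Within each list, p was also adjusted over the list alone. GO and KEGG terms of 10 to 500 tested genes were tested by a one-sided Fisher's exact test for higher and lower genes separately, with all tested genes as background.

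Genes named in the text followed a rule fixed in advance. It took 11 genes of the study's topic (Hif1a, Vegfa, Slc2a1, Hk2, Ldha, Pecam1, Cd8a, Cd274, Alb, Afp and Mki67), and the 10 largest changes in each direction among genes that passed, had a symbol that is not a locus or clone name, a mean FPKM of at least 1 and groups that did not overlap. It also took up to 3 members that passed from each list that camera called or that had at least 3 such members. Of the genes the rule took, 1 is not reported here. Other members of lists and terms are named as examples chosen after their values were seen.

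The scripts were tested on simulated counts for TAE against HCC with 200 changed genes drawn from the real means and library sizes, of which 14300 genes passed the filter. There edgeR recovered 44.8% of genes changed 2-fold, 98.5% of those changed 4-fold and 100% of those changed 8-fold, and called 0.0709% of unchanged genes. The changed genes were drawn only from those above a set mean CPM. Genes were simulated independently, with the same dispersion in both groups. These rates thus do not cover genes with low counts, genes that vary together or the wider spread between the TAE libraries. Total counts were 13448286 to 16604067 per library, so that counting error was small for abundant genes and larger for those near 1 FPKM. Alternatives were pseudocounts, filters, scalings, sample weights, a replicate block, DESeq2 (1.42.0), fold and p thresholds, term sizes, and leaving out each library in turn. Chosen after seeing the data were DESeq2 without each library and with the block, the counts at an unadjusted p in those fits, and list medians under other scalings. Groups of 3 are too small for an outlier test per gene, so no gene was examined for single aberrant samples.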

Results

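RNA from rat liver tissue was sequenced in 2 groups of 3 libraries each. The HCC group, from rats of a hepatocellular carcinoma study, received no treatment and served as the control. The TAE group underwent transarterial embolization, a procedure in which the arteries that feed a liver tumour are blocked. Expression of 32623 annotated genes was given as read counts and as FPKM (fragment counts scaled to exon length and library total), and 10988 genes had no count in any library. The total count per library was 14370846, 13448286 and 14138652 for HCC replicates 1 to 3 and 14552885, 16578929 and 16604067 for TAE replicates 1 to 3. The HCC libraries resembled each other more than the TAE libraries did. Across genes, the Pearson correlation of log2 CPM (counts scaled to the library total) between replicates was 0.984 to 0.991 within HCC and 0.935 to 0.969 within TAE, and genes are not independent replicates. TAE replicate 2 correlated at 0.967, 0.969 and 0.968 with HCC replicates 1, 2 and 3. These values exceed its 0.935 with TAE replicate 3 and are near its 0.969 with TAE replicate 1. TAE replicates 1 and 3 were closer to each other (0.962) than to any HCC library (0.924 to 0.951). Albumin (Alb), the main plasma protein made by hepatocytes, took 2.50%, 3.07% and 3.28% of the counts in the HCC libraries and 1.44%, 1.10% and 3.17% in TAE replicates 1 to 3.

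The comparison of TAE with HCC asked which genes differed in liver tissue after embolization. Genes expressed by phagocytic myeloid cells were among those that rose after TAE. Gpnmb, a transmembrane glycoprotein of lysosome-rich macrophages, rose from 173 ± 26.1 FPKM in HCC to 882 ± 277 FPKM in TAE (mean ± SD, n = 3 per group), a log2 change of 2.35 ± 0.33 (SE). Lyz2, the lysozyme of myeloid cells, rose from 801 ± 124 to 3226 ± 388 FPKM, a log2 change of 1.97 ± 0.23. Single genes of hepatic steroid and drug metabolism were among those that fell. Cyp2c11, a steroid hydroxylase of liver, fell from 183 ± 19.6 to 30.1 ± 6.29 FPKM, a log2 change of -2.66 ± 0.17, and Cyp2c12, another steroid hydroxylase, fell from 377 ± 77.9 to 103 ± 24.2 FPKM, a log2 change of -1.89 ± 0.29. In edgeR's quasi-likelihood test, 437 of 14499 genes passed an adjusted p of 0.05, of which 392 were higher and 45 lower in TAE, and 349 of them changed by at least 1 on the log2 scale (318 higher and 31 lower). The groups did not overlap for 3985 genes (27.5% of those tested), where chance gives 10% on average. Genes vary together, so the share can stray far from 10% by chance, and it was not computed for other splits. The count of calls rested on single libraries: edgeR called 0, 1 and 0 genes without HCC replicates 1, 2 and 3, 1 gene without TAE replicate 1, 3569 without TAE replicate 2 and 1226 without TAE replicate 3. In these fits 2210, 2243, 1997, 2197, 5878 and 3749 genes had an unadjusted p under 0.05, and DESeq2 called 890, 1034, 713, 769, 4234 and 2118. DESeq2 on all 6 libraries called 1763 genes, all 437 among them, and limma called 701 on log2(FPKM + 1) but 17 (8 higher and 9 lower) once median-of-ratios scaling was applied.

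The named genes with the largest rise were Chp2, Cd300lb, Trem2, Fcrl2, Mcpt1l1, Bhlhe41, Tm4sf19, Itm2a and Lpar4, with log2 changes from 3.66 down to 2.56. Trem2, a lipid-sensing receptor of macrophages (gene ENSRNOG00000013578, chromosome 9, 14611561 to 14618013), rose from 2.55 ± 1.43 to 26.3 ± 12.7 FPKM, a log2 change of 3.37 ± 0.59 (edgeR adjusted p = 0.0406, higher in 3 of 3 TAE libraries than in any HCC library). Cd300lb, an activating receptor of myeloid cells, rose from 0.260 ± 0.0872 to 2.85 ± 1.5 FPKM, and Mcpt1l1, a relative of mast cell protease 1, from 0.583 ± 0.297 to 4.86 ± 1.45 FPKM. Itm2a, an integral membrane protein, was the most abundant of these in TAE and rose from 8.91 ± 2.35 to 55.1 ± 24.8 FPKM. The 10 named genes with the largest fall were Dhrs7l1, Cyp2c11, Akr7a3, Gstm3l, Mup5, Mettl7b, Cyp2c24, Cyp2c12, Gimd1 and Cyp4a3, with log2 changes from -2.71 to -1.79. Cyp2c11 (gene ENSRNOG00000052810, chromosome 1, 257970345 to 258004434) had the smallest adjusted p of all genes (edgeR, 0.0111). Akr7a3, an aldehyde reductase that detoxifies aflatoxin (gene ENSRNOG00000017899, chromosome 5, 157801163 to 157813756), fell from 23.9 ± 2.49 to 4.75 ± 1.49 FPKM, a log2 change of -2.41 ± 0.20 (edgeR adjusted p = 0.0365). Mup5, a member of the major urinary protein family secreted by liver, fell from 173 ± 62.9 to 34.0 ± 12.0 FPKM. Values of Cyp2c, Cyp4a, Gstm, Mup and Mcpt1 genes are uncertain as single genes, because each family has close copies whose reads the counting could have split. Coordinates are those of the deposited table, whose gene ends on chromosome 1 reach 282724300, beyond the known length of that chromosome in mRatBN7.2, the build in the submitters' processing notes, so their build is not settled.

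**Figure D1:**
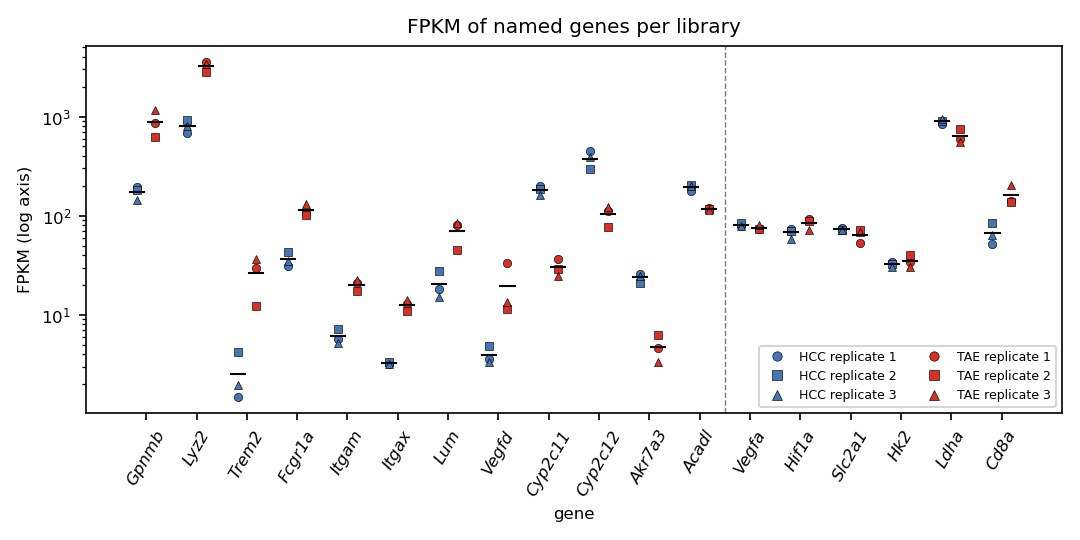
FPKM (log axis) of 18 named genes in each library, with HCC in blue and TAE in red, symbols for the replicate number and a black line at each group mean (n = 3 per group). The 12 genes left of the dashed line passed the edgeR test, and Gpnmb lies at 173 FPKM on average in HCC and at 882 in TAE, while the 6 genes on the right did not pass.

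Some members of each of 3 myeloid lists rose. Camera called these lists, but none held when correlation was estimated (adjusted p = 0.59 with an estimated correlation for each). With fry, adjusted p was 0.153 for the macrophage list and 0.110 for both others. Of 18 macrophage and monocyte markers tested, 8 rose (Cd68, Csf1r, Msr1, Lyz2, Trem2, Gpnmb, Fcgr1a and Aif1), none fell and 10 did not pass, and 13 rose when p was adjusted over the list alone. Fcgr1a, the high-affinity IgG receptor, rose from 36.4 ± 6.18 to 113 ± 16.4 FPKM. The list median was a log2 change of 1.18 (limma camera, adjusted p = 2.95e-06). Of 10 neutrophil markers tested, 3 rose (Itgam, Ncf1 and Ncf4) and 7 did not pass, and 8 rose with p adjusted over the list alone (median log2 change 1.47, camera adjusted p = 6.88e-05). Mpo, Camp, Ltf, Fpr1, Fpr2, Retnlg and Cxcr1 of the same list had too few counts to be tested, so all values of this list leave them out. Itgam, an integrin chain of neutrophils and macrophages alike, rose from 6.05 ± 0.967 to 20.2 ± 2.73 FPKM, and Ncf1 and Ncf4, subunits of the phagocyte NADPH oxidase, are likewise expressed by both cell types. Of 19 dendritic cell and MHC class II genes, 4 rose (Itgax, Cd80, Cd83 and Ciita) and 15 did not pass, and 13 rose with p adjusted over the list alone (median log2 change 1.01, camera adjusted p = 2.95e-06). Itgax, the CD11c integrin chain, rose from 3.24 ± 0.0814 to 12.7 ± 1.65 FPKM. Cd80, a costimulatory ligand, rose from 0.783 ± 0.101 to 2.93 ± 0.675, and Ciita, the transactivator of MHC class II genes, from 12.4 ± 1.33 to 24.4 ± 3.36. Without TAE replicate 2, 13 macrophage, 8 neutrophil and 13 dendritic cell genes rose over all genes while 1 dendritic cell gene fell, and without TAE replicate 3, 11, 4 and 11 rose while 2 macrophage genes fell. Without TAE replicate 1, 0 genes of these 3 lists passed over all genes. Without HCC replicates 1, 2 and 3, edgeR called only 0, 1 and 0 genes of all those tested. Relative to the HCC mean, the macrophage list stood at 0.96, 0.45 and 1.78 on the log2 scale in TAE replicates 1, 2 and 3.

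Camera called 5 lists of connective tissue, duct and vessel wall genes higher in TAE, with few single calls. All 20 fibrosis and extracellular matrix genes tested had positive log2 changes with a median of 1.51 (camera adjusted p = 8.28e-07, adjusted p = 0.59 with an estimated correlation). Of these, Lum alone passed over all genes and 15 rose with p adjusted over the list alone. Lum, the small matrix proteoglycan lumican, rose from 20.3 ± 6.46 to 70.3 ± 22.0 FPKM, a log2 change of 1.78 ± 0.35. The collagen gene Col3a1 stood at 242 ± 54.1 FPKM in HCC and 915 ± 489 in TAE (log2 change 1.87, edgeR adjusted p = 0.0520). None of 11 pericyte and smooth muscle markers passed over all genes and 7 did with p adjusted over the list alone (median log2 change 1.01, camera adjusted p = 0.00019). Of 11 cholangiocyte and ductular markers, Cftr, the epithelial chloride channel, rose from 0.273 ± 0.118 to 1.37 ± 0.534 FPKM, and 5 rose with p adjusted over the list alone (median log2 change 0.83, camera adjusted p = 0.00144). None of 15 endothelial markers passed over all genes and 3 rose with p adjusted over the list alone (median log2 change 0.60, camera adjusted p = 0.00111, but 0.0684 without TAE replicate 3). Of 21 angiogenic ligands and receptors, Vegfd, a growth factor for lymphatic vessels, rose from 3.94 ± 0.824 to 19.4 ± 12.1 FPKM, and 5 rose with p adjusted over the list alone (median log2 change 0.48, camera adjusted p = 0.0261, but 0.0702 without TAE replicate 3 and 0.18 at a mean FPKM of at least 5). Without TAE replicate 2 the genes that rose over all genes became 15, 6, 5, 11 and 10 for these 5 lists in the order named, and without TAE replicate 3 they became 7, 4, 3, 2 and 3, while 1 endothelial gene fell. Without TAE replicate 1, 0 genes of these 5 lists passed over all genes. The calls of the pericyte, cholangiocyte, endothelial and angiogenic lists were lost as well (adjusted p = 0.59 with an estimated correlation).

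Lymphocyte genes differed between the TAE libraries. None of 23 T and NK cell and cytotoxicity genes passed over all genes and 3 did with p adjusted over the list alone, namely Cd4, Cd8a and Ncr1. Cd8a, the coreceptor of cytotoxic T cells, stood at 66.4 ± 16.0 FPKM in HCC and 161 ± 36.1 in TAE, a log2 change of 1.25 ± 0.28 (edgeR adjusted p = 0.0606), whereas the T cell receptor component Cd3e and the cytotoxic effector Prf1 had log2 changes of 0.10 and 0.08. The list median was 0.40 (camera adjusted p = 0.0261, adjusted p = 0.67 with an estimated correlation), and the list stood at -0.17, 0.18 and 1.12 relative to the HCC mean in TAE replicates 1, 2 and 3. Its camera adjusted p was 0.171 without HCC replicate 1, 0.0752 without TAE replicate 2 and 0.769 without TAE replicate 3. None of 11 B and plasma cell markers passed over all genes and 4 rose with p adjusted over the list alone (median log2 change 0.76, camera adjusted p = 0.0352, adjusted p = 0.59 with an estimated correlation, 0.0999 without TAE replicate 3). The median was smaller in all 4 limma scalings, at 0.34 to 0.44, and the list stood at 0.43, 0.36 and 1.75 relative to the HCC mean in TAE replicates 1, 2 and 3. Of 15 immune checkpoint genes, Tgfb1, an immunosuppressive cytokine, rose from 30.8 ± 2.37 to 59.3 ± 4.20 FPKM, and 4 rose with p adjusted over the list alone (median log2 change 0.40, camera adjusted p = 0.0352, adjusted p = 0.59 with an estimated correlation). The call of the checkpoint list was lost without HCC replicate 1 or 3 and without TAE replicate 2 or 3 (camera adjusted p = 0.0559, 0.0572, 0.0903 and 0.166), as well as with limma on log2(FPKM + 1), pseudocount 0.1, quantile normalization and a mean FPKM of at least 5 (0.0612, 0.0681, 0.0685 and 0.124). The B and plasma cell call was also lost without an FPKM filter and with quantile normalization (camera adjusted p = 0.0509 and 0.0528), and the smallest medians of the T and NK cell and checkpoint lists over 5 other scalings were 0.24 and 0.20. Cd274, which encodes the ligand PD-L1, stood at 13.6 ± 2.56 FPKM in HCC and 21.1 ± 1.47 in TAE, a log2 change of 0.59 ± 0.18 that did not pass over all genes (edgeR adjusted p = 0.118).

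Among signalling and cell death genes, Csf1, the growth factor of macrophages, rose from 7.57 ± 0.526 to 13.3 ± 1.34 FPKM and was the only one of 24 inflammatory cytokine and chemokine genes to pass over all genes, with 5 rising when p was adjusted over the list alone. The median log2 change of this list was 0.32 (camera adjusted p = 0.0261, adjusted p = 0.59 with an estimated correlation), and the call was lost without HCC replicate 1 (0.129) and without TAE replicate 2 (0.126). Of 17 apoptosis and necroptosis genes, Bcl2l11, which encodes the pro-apoptotic protein Bim, rose from 6.62 ± 0.534 to 10.9 ± 0.794 FPKM, and 5 rose with p adjusted over the list alone, among them Mlkl, the effector of necroptosis (log2 change 0.84 ± 0.18, edgeR adjusted p = 0.0533 over all genes). The median of this list was 0.40 (camera adjusted p = 0.00571, adjusted p = 0.59 with an estimated correlation), and it was the only list that limma's fry called (adjusted p = 0.0284). Under 5 other scalings the median was 0.20 to 0.40.

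Camera called 4 lists of hepatic metabolism and identity lower in TAE, with 2 single genes that fell. All 19 fatty acid oxidation and ketogenesis genes tested had negative log2 changes with a median of -0.56 (camera adjusted p = 8.64e-06), and the list stood at -0.77, -1.04 and -0.18 in TAE replicates 1, 2 and 3. Acadl, the long-chain acyl-CoA dehydrogenase, fell from 194 ± 15.0 to 117 ± 2.61 FPKM, Bdh1, which interconverts ketone bodies, fell from 51.5 ± 5.38 to 27.3 ± 3.14 FPKM, and 6 genes fell with p adjusted over the list alone. Over all genes 3 of the 19 fell without TAE replicate 2 and 11 without TAE replicate 3, and for the next list these counts were 7 and 6. Without TAE replicate 1, 0 genes of the 4 lists in this paragraph passed over all genes. Of 19 cholesterol and fatty acid synthesis genes, 18 had negative log2 changes, none passed over all genes and 4 fell with p adjusted over the list alone (median -0.39, camera adjusted p = 6.88e-05). None of 24 hepatocyte markers passed by either adjustment (0 adjusted over the list alone), and 22 had negative log2 changes (median -0.52, camera adjusted p = 0.000896). The hepatocyte list stood at -0.85, -1.56 and 0.24 relative to the HCC mean in TAE replicates 1, 2 and 3. Without TAE replicate 2 its camera adjusted p was 0.138 and 0 of its genes passed, whereas without TAE replicate 3 it was 3.26e-12 and 14 of the 24 fell over all genes. None of 30 mitochondrial respiration genes passed by either adjustment (0 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.0261, but 0.0904 without HCC replicate 2 and 0.192 without TAE replicate 1), while 6 fell over all genes without TAE replicate 2. The mitochondrial call was also lost in 6 limma settings, with camera adjusted p from 0.0509 without an FPKM filter to 0.386 with quantile normalization, where the median was -0.05. The calls of these 4 lists were lost when the correlation between genes was estimated (adjusted p = 0.59 with an estimated correlation). Alb stood at 14272 ± 1952 FPKM in HCC and 9190 ± 5358 in TAE, a log2 change of -0.62 ± 0.48 (edgeR adjusted p = 0.446).

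Cell cycle genes were lower in TAE replicate 3 in particular. All 24 cell cycle and mitosis genes tested had negative log2 changes with a median of -0.50, and none passed by either adjustment (0 adjusted over the list alone, camera adjusted p = 0.00019, adjusted p = 0.59 with an estimated correlation), while 3 fell over all genes without TAE replicate 2. Without TAE replicate 1 or 3, 0 of them passed over all genes. The list stood at -0.37, -0.01 and -1.38 relative to the HCC mean in TAE replicates 1, 2 and 3. Mki67, the proliferation marker Ki-67, stood at 29.1 ± 4.55 FPKM in HCC and 26.1 ± 10.9 in TAE, a log2 change of -0.25 ± 0.27 (edgeR adjusted p = 0.592) that became 0.038 without TAE replicate 3. None of 13 oncofetal and liver tumour markers passed over all genes, 3 rose and 1 fell with p adjusted over the list alone, and the list was not called (median 0.58, camera adjusted p = 0.395). This median depended on the scaling and was 0.18, 0.15 and 0.14 with limma on log2(FPKM + 1), quantile normalization and median-of-ratios scaling. Afp, the fetal serum protein used as a tumour marker, was low in both groups at 1.82 ± 0.326 and 1.55 ± 0.450 FPKM (log2 change -0.25 ± 0.35, edgeR adjusted p = 0.668).

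**Figure D2:**
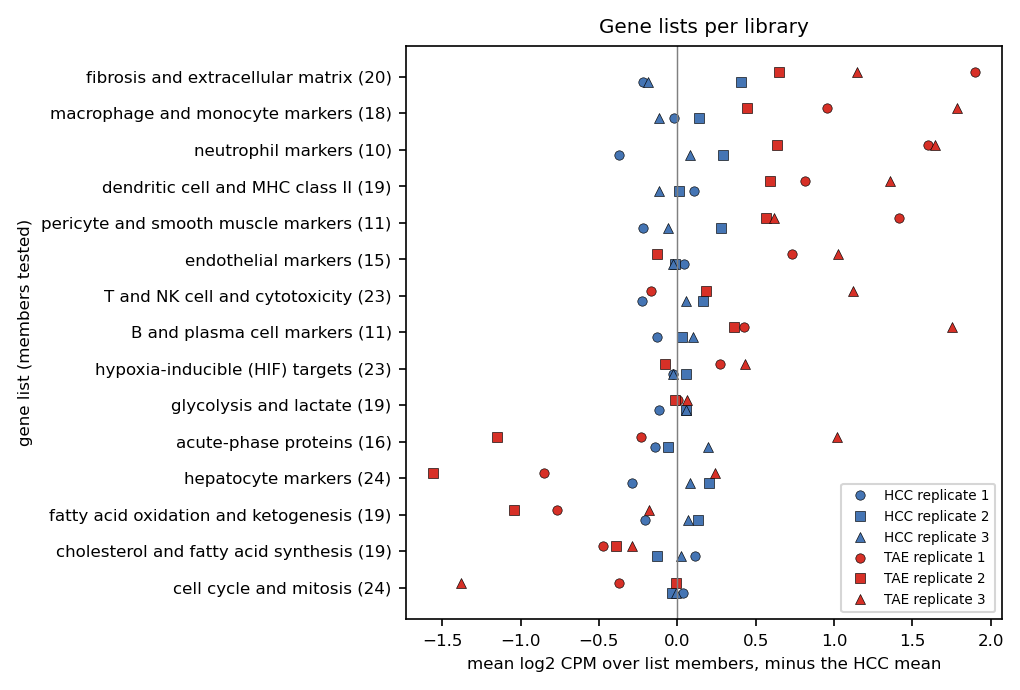
Mean log2 CPM over the tested members of 15 gene lists in each library, minus the mean of the 3 HCC libraries, with HCC in blue and TAE in red and symbols for the replicate number. The fibrosis and extracellular matrix list stands at 1.90, 0.65 and 1.15 in TAE replicates 1 to 3, whereas the hepatocyte list stands at -0.85, -1.56 and 0.24.

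Hypoxia and glycolysis were covered by 2 lists and by genes named in advance, of which 1 gene passed over all genes. None of 23 hypoxia-inducible (HIF) targets passed over all genes, 2 rose and 1 fell with p adjusted over the list alone, and the list was not called (median log2 change 0.05, camera adjusted p = 0.533). Vegfa, the main angiogenic ligand induced by hypoxia, stood at 81.0 ± 3.33 FPKM in HCC and 75.8 ± 4.66 in TAE (log2 change -0.13 ± 0.16, edgeR adjusted p = 0.621). Hif1a, the oxygen-regulated transcription factor subunit, stood at 67.8 ± 8.08 and 84.0 ± 11.4 FPKM (0.25 ± 0.14, adjusted p = 0.309). Of 19 glycolysis and lactate genes, Pfkp, the platelet-type phosphofructokinase, rose from 9.84 ± 0.680 to 19.7 ± 2.93 FPKM, and 2 rose and 2 fell with p adjusted over the list alone. The list was not called (camera adjusted p = 0.236), and its median of -0.22 and its mean of 0.03 differed in sign. The glucose transporter Slc2a1 and the hexokinase Hk2 had log2 changes of -0.22 ± 0.17 and 0.04 ± 0.11 (edgeR adjusted p = 0.436 and 0.831). Ldha, a subunit of lactate dehydrogenase, stood at 894 ± 51.5 FPKM in HCC and 631 ± 106 in TAE, a log2 change of -0.57 ± 0.15 that did not pass over all genes (edgeR adjusted p = 0.0849).

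Among the remaining lists fixed before the data were examined, camera called none with all 6 libraries. Without TAE replicate 3 it called the acute-phase, sulfide metabolism and oxidative stress lists lower (camera adjusted p = 0.0001005, 0.0224 and 0.0356). MHC class I processing was called higher without TAE replicate 1 (camera adjusted p = 0.0263) and with 3 of the limma settings, namely no FPKM filter, a mean FPKM of at least 5 and quantile normalization (0.0128, 0.0202 and 0.0124). Of 16 oxidative stress and metallothionein genes, Osgin1, a stress-induced growth inhibitor, fell from 51.8 ± 4.77 to 22.6 ± 0.946 FPKM, and 2 rose and 2 fell with p adjusted over the list alone (camera adjusted p = 0.146). No gene passed over all genes among 13 MHC class I processing, 21 interferon response, 16 acute-phase, 18 stress and unfolded protein response, 9 red blood cell, 6 sulfide metabolism and 6 adipocyte genes. Adjusted over the list alone, 1 acute-phase gene rose and 1 fell, 1 sulfide metabolism gene and 2 adipocyte genes rose, and 0 passed in the other 4 lists. Their camera adjusted p were 0.128, 0.211, 0.349, 0.378, 0.446, 0.517 and 0.901 in the order named. The acute-phase list stood at -0.23, -1.15 and 1.02 relative to the HCC mean in TAE replicates 1, 2 and 3, and its median (-0.07) and mean (0.20) differed in sign, as did those of the adipocyte list (-0.17 and 0.14). The acute-phase median was lower in the 4 limma scalings, from -0.45 to -0.32. With 3 platelet, 4 skeletal muscle, 3 mesothelial and 2 pancreatic acinar markers tested, those lists were too short for camera. Pf4, the platelet factor 4 chemokine, rose from 8.76 ± 2.99 to 47.5 ± 17.6 FPKM and was the only member of these 4 lists to pass over all genes. Adjusted over the list alone, 1 platelet and 1 mesothelial gene rose and 0 skeletal muscle and 0 pancreatic genes passed.

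Annotation terms in the deposited table were tested for enrichment among the called genes. Among the 392 higher genes, inflammatory response held 31 of its 218 tested genes against 5.89 by chance, including the complement receptors C3ar1 and C5ar1, Nlrp3 and Ptafr (Fisher's exact test, adjusted p = 7.03e-11). The osteoclast differentiation pathway held 24 of 127, among them the myeloid signalling genes Spi1, Syk, Tyrobp, Btk and Csf1r (adjusted p = 7.03e-11, Fisher's exact test). The natural killer cell cytotoxicity pathway held 17 of 95, among them Fcer1g, Syk, Tyrobp and Vav1, which myeloid cells use as well (adjusted p = 4.95e-07, Fisher's exact test). Phagocytosis and engulfment held 9 of 26, including Aif1, Msr1, Itgam and Fcgr1a (adjusted p = 7.74e-06, Fisher's exact test). Among the 45 lower genes, chemical carcinogenesis held 9 of 70 against 0.217 by chance and retinol metabolism 8 of 60 against 0.186 (Fisher's exact test, adjusted p = 2.05e-09 and 1.61e-08), and both hold Cyp2c11, Cyp2c12, Cyp2c24 and Cyp3a9. The chemical carcinogenesis genes also include the epoxide hydrolase Ephx1 and the glutathione transferases Gstm1 and Gstm3l. These pathways as a whole were closer to HCC in TAE replicate 3 than in the other 2 TAE libraries. The median over all tested chemical carcinogenesis genes was -0.83, -1.29 and -0.02 relative to the HCC mean in TAE replicates 1, 2 and 3. For retinol metabolism it was -0.80, -1.34 and -0.03. For xenobiotic metabolism by P450, of which 4 of 50 genes fell, it was -0.64, -0.97 and 0.06. The means in TAE replicate 3 were -0.20, -0.27 and -0.03 in the same order. In all, 67 terms passed among higher and 28 among lower genes of 3171 tested in each direction, and genes of 1 term are not independent. Most of the 28 lower terms repeat Cyp2c11, Cyp2c12 and Cyp2c24, and several others repeat Mup5, so they are not separate results. These are families of close copies whose reads the counting could have split. The total of 95 terms became 342 without TAE replicate 2 and 362 without TAE replicate 3, and with fewer than 10 calls per direction no term test was made without any of the other 4 libraries.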

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

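DESeq2 without each library and with the block, and the unadjusted counts in those fits, were chosen after the data were seen, and the other alternatives in this part before. The 437 genes became 0 to 3569 when each library was left out, 701 with limma on log2(FPKM + 1), 709 with pseudocount 0.1, 660 at a mean FPKM of at least 5, 659 as TPM, 17 with median-of-ratios scaling, 689 without a mean-variance trend, 9590 with sample weights (whose fit did not converge), 829 with edgeR without a filter, 1763 with DESeq2, 1667 with DESeq2 without a filter and 0 at an adjusted p under 0.01, where DESeq2 called 1031 and 3296 had an unadjusted p under 0.05 in edgeR. No FPKM filter gave 364 genes, quantile normalization 410 and a log2 limit of 1 gave 349. Of the 437 genes, 436 had an adjusted p over 0.03, near the threshold of 0.05, and the cause of the other shifts was not tested. The 18 lists became 0 with an estimated correlation and 1 with fry, and were 14 to 18 in the other alternatives, of which 13 to 18 were among the main 18, with no called list turning direction. The 95 terms ranged from 342 to 362 without TAE replicates 2 and 3, and were 83 with a log2 limit of 1, 90 with terms of 20 to 300 genes and 131 with quantile normalization. The terms could not be tested with the block or without the other 4 libraries, which left under 10 genes per direction, and were not tested in the remaining alternatives.

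The labels do not say whether the replicate numbers pair the samples, and 3 libraries per group are too few to decide it from the values. Correlations of deviations from the group means were 0.10, -0.21 and 0.03 for the same numbers, and with the numbers as a block edgeR called 0 genes (2984 at an unadjusted p under 0.05, DESeq2 1254) and camera 18 lists. Of 611 values of named genes under alternatives, 365 kept their direction and side of the threshold, 232 lost the call, 13 gained it and 1 reversed: Mki67, which ranged from -0.45 without TAE replicate 1 to 0.038 without TAE replicate 3. Depth was similar in all libraries, and genes under 1 FPKM are limited by their counts.

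Other splits of the 6 libraries into 3 and 3 number 10 with the real split, too few for a share under 0.05. As many genes came from 1 of the 10 splits, the real one (437, highest other 0), and as many lists from 1 of the 10 (18, highest other 14). The 9 other splits, which mix the groups, still gave 6 to 14 lists each. Camera with the preset correlation thus called lists under mixed groupings too. Those splits keep part of the real contrast and of the differences between the TAE libraries, so their list counts alone cannot show that its adjusted p-values are too small. They may be too small here, since 0 of the 18 lists held with an estimated correlation. Mixing the groups also widens the spread within each, which lowers the number of genes called in such splits.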

Other observations

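The marker sets and tests in this part were all chosen after the results were seen. Of 9 mast cell genes tested, the proteases Mcpt1 (from 7.01 ± 0.0493 to 28.9 ± 11.6 FPKM, n = 3 per group) and Mcpt1l1 rose (edgeR adjusted p = 0.0398 and 0.0388), and the other 7 did not pass, among them Cpa3, a mast cell carboxypeptidase, with a log2 change of 2.36 ± 0.49 (adjusted p = 0.0516) and Fcer1a, the IgE receptor chain, with 2.54 ± 0.57 (adjusted p = 0.0594). The histamine-forming enzyme gene Hdc had a log2 change of -0.77 ± 0.27. The mean of the 9 genes, for which no set test was made, stood at 1.38, 1.13 and 2.31 relative to the HCC mean in TAE replicates 1, 2 and 3. Some single genes of myeloid cells, picked as examples with no count of others, also rose. Spi1, the transcription factor PU.1, rose from 19.4 ± 1.58 to 46.1 ± 4.41 FPKM, Irf5 from 10.5 ± 1.30 to 27.2 ± 3.71 and Irf8 from 39.6 ± 3.21 to 75.4 ± 3.15, each with an edgeR adjusted p of 0.0388. The receptor adaptors Tyrobp and Fcer1g, which signal through Syk, had log2 changes of 1.28 ± 0.21 and 1.45 ± 0.25, and Syk itself 1.44 ± 0.23.

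Markers of resident liver cells differed between the TAE libraries. Marco, Vsig4, Clec4f and Cd5l, genes of resident Kupffer cells, had a mean of -0.79, -1.34 and 0.97 relative to HCC in TAE replicates 1, 2 and 3. The sinusoidal endothelial genes Stab2, Lyve1, Clec4g, Oit3 and Clec1b had -0.45, -1.29 and 1.08. None of these 9 genes passed the test between the groups. Macrophage genes such as Trem2, Gpnmb and Lyz2 were higher in all 3 TAE libraries, so that they and the Kupffer genes moved apart in TAE replicates 1 and 2.

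The first pattern weighed is the rise of macrophage genes in TAE. A lower share of the main cell type would raise the markers of other types alike. The macrophage list rose by 0.68 ± 0.27 (SE over libraries) more than the T and NK cell list on the log2 scale. Mean log2 changes were 1.415 for neutrophil, 1.33 for fibrosis, 1.19 for macrophage, 1.13 for B and plasma cell and 1.08 for cholangiocyte genes. They were 0.98 for dendritic cell, 0.92 for pericyte, 0.69 for endothelial and 0.49 for T and NK cell genes. Several lists rose about as much as the macrophage list, so a lower share of the main cell type stays open as part of the cause. In TAE replicates 1 and 2, however, the Kupffer genes stood at -0.79 and -1.34 relative to the HCC mean. The T and NK cell list stood at -0.17 and 0.18 there. Such values argue against a lower share as the whole cause in TAE replicates 1 and 2. Library scaling alone is argued against, since the smallest median of the macrophage list over 5 other scalings was 1.07. More macrophages, or more expression per macrophage, after embolization stays open as a hypothesis and was not tested.

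The next pattern is the low level of cell cycle genes in TAE replicate 3. Abundant liver transcripts taking more of the counts would lower all other genes alike, but there the cell cycle list minus the median of all tested genes was -1.39, which argues against this. A larger share of non-tumour liver in that library may contribute. Against both other TAE libraries, 4 of the 4 sets needed moved as such a share requires. The hepatocyte, Kupffer and sinusoidal sets were higher and the fetal genes Igf2bp1, Igf2bp3, Lin28b and Hmga2 lower. That comparison does not test the fall against HCC. Relative to the HCC mean, the hepatocyte list stood at 0.24 in TAE replicate 3, near the 0.21 of HCC replicate 2. The Kupffer and sinusoidal sets stood at 0.97 and 1.08 in TAE replicate 3. In TAE replicate 2 the hepatocyte list was at -1.56, but the cell cycle list was at -0.01. The 4 fetal genes belong to the oncofetal and liver tumour list, where 7 genes had positive and 6 negative log2 changes. The values of the 4 sets had been seen, so they cannot establish a larger share of non-tumour liver. A stronger response to embolization in that sample stays open as a hypothesis and was not tested.

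The last pattern is the 45 genes called lower, P450 genes among them, which stood at -1.57, -1.70 and -1.51 relative to HCC in TAE replicates 1, 2 and 3 and were chosen for being lower. The wider pathways shared little of this in TAE replicate 3, where the means over all members of the retinol, chemical carcinogenesis and xenobiotic pathways were -0.27 ± 0.13, -0.20 ± 0.11 and -0.03 ± 0.13 (SE over members) and the medians -0.03, -0.02 and 0.06. Fewer hepatocytes in that library are argued against as the whole cause for the 45 genes, since the hepatocyte list stood at 0.24 ± 0.13 (SE over members) there. That SE does not measure the spread between libraries. HCC replicates 1, 2 and 3 stood at -0.29, 0.21 and 0.08 on this list. In TAE replicates 1 and 2 the hepatocyte list averaged -1.20, and fewer hepatocytes may account for the lower pathway values and part of the 45 genes' fall there. The Kupffer genes stood at -0.79 and -1.34 and the sinusoidal genes at -0.45 and -1.29 in these libraries. The labels do not say whether tumour alone or tumour with surrounding liver was taken. A smaller share of non-tumour liver in TAE replicates 1 and 2 thus cannot be told apart from other causes. Lower expression of these 45 genes in the remaining hepatocytes stays open as a hypothesis.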
